A study of Mus musculus with 6 samples.

How the data were processed

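RNA was measured in 6 mouse T cell cultures by stranded mRNA sequencing, per the labels' protocols. Splenic CD4+CD62L+ T cells of wild-type and Il17a knockout mice on the B10.RIII background were cultured for 3 days under Th17-polarizing conditions, with IL-6 and IL-23 at 10 ng/ml each, TGF-β at 1 ng/ml, and blocking antibodies against IFN-γ and IL-4 at 10 µg/ml each. Each genotype had 3 libraries that the labels call biological replicates, numbered 1 to 3.

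The deposited table gave, per the file headers, an estimated count for each of 93480 transcripts in each library. Bowtie2 2.1.0, eXpress 1.3.1 and the genome build GRCm38 are named in the submitters' processing notes. The annotation release and the counting settings are not given in the sources used here. Only 0.02% of the values above 0.5 were whole within 1e-04, so the values were read as estimated counts. The smallest cluster of values lay at 1.54 to 1.55 for transcripts of 400 to 700 nt and at 1.02 to 1.08 for transcripts over 5000 nt. A read of a short transcript therefore carried more than 1 estimated count, and short transcripts have less depth behind them than their counts show. The deposited table also gave each transcript's length and its GC content as a fraction. GC content entered no test, and length served only to set transcripts under 300 nt apart.

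Estimated counts were summed over the transcripts of each of 38483 genes and rounded to whole numbers. No column of per-sample values was left unused. Totals ran from 47335736 to 49743762 estimated counts per library. A count of 0 in a library allows up to 3 counts, about 0.06 CPM, and these floors cover counting error only. CPM values were counts divided by TMM-scaled library sizes. No pair of libraries agreed within sampling noise: chi-square per degree of freedom over genes ran from 56.8 to 273.7.

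The main comparison, fixed before the data were examined, was edgeR 4.0.16's quasi-likelihood test of knockout against wild-type with TMM scaling, filterByExpr at its defaults and no block. It ran on 15121 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were also used.

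The 2 genotypes share the replicate numbers 1 to 3. The labels do not say what a number marks, so pairing was checked from the data by a rule set in advance, that every same-number correlation exceed 0.1. Deviations from the group mean correlated at 0.48, 0.33 and 0.49 across genes between libraries of the same number, and at -0.13 to -0.36 between libraries of different numbers. All 6 libraries matched their own number best, so the numbers were taken to pair the samples. Deviations from a group mean cancel within each genotype, so positive same-number correlations force some negative ones elsewhere. The 6 best matches are therefore not independent. So few libraries allow few pairings, and chance agreement with the numbers is not excluded. Below, pair 1 is knockout 1 with wild-type 1, and so on. edgeR's common dispersion was 0.169 without and 0.0601 with the replicate number as a block. The paired fit in edgeR was planned. The paired fits in DESeq2 and in limma-voom were added after seeing the data. Of the 15121 genes, 880 had no adjusted p in the paired DESeq2 fit and were not counted as called or as lost. Log2 ratios within a pair were taken of CPM + 0.5.

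Each fit was tested on simulated counts drawn from the real means, spreads and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Without the block, on 14747 genes, edgeR recovered 13% of the 2-fold and 70% of the 4-fold changes, DESeq2 42% and 87%, and limma-voom 11% and 62%. With the block, on 14752 genes, edgeR recovered 74% and 87%, DESeq2 87% and 94%, and limma-voom 74% and 89%. Of all calls, unchanged genes made up 7.8% in edgeR, 32.5% in DESeq2 and 3.9% in limma-voom without the block, and 8.5%, 23.3% and 10.4% with it. Every fit but limma-voom without the block thus exceeded the nominal rate of 0.05, DESeq2 by the most. These shares rest on simulated 2-fold and 4-fold changes only, so they need not hold for smaller changes. With no gene changed, the calls without the block were 0 in edgeR, 34 in DESeq2 and 0 in limma-voom, and with the block 7, 25 and 11. The draws for the fits without the block left out the replicate structure of the real libraries, so their figures need not hold for the real data. With no gene changed, edgeR without the block put 4.71% of simulated genes at an unadjusted p under 0.05, against 1.67% of the real genes. edgeR's estimated prior degrees of freedom were 2.91 without and 3.55 with the block.

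A total of 30 gene lists were fixed before the data were examined: the Th17 program, pathogenic and non-pathogenic Th17 genes, IL-10 family cytokines and receptors, SOCS and cytokine feedback, IL-17 receptor signalling, IL-17 target genes of other tissues, NF-kB, Th1, Th2, regulatory T cell, naive T cell, T cell identity, T cell activation, interferon-stimulated, glycolysis and hypoxia, mitochondrial respiration, cell cycle, cholesterol synthesis, ER and amino acid stress, heat shock, markers of B, CD8 T, NK, myeloid, dendritic and gamma-delta T cells, erythroid and platelet markers, and neighbours of Il17a on chromosome 1. Their 488 entries held 466 distinct symbols, of which 454 matched a gene by symbol. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, over lists with at least 3 tested members. The estimated correlation and fry were run in edgeR only. No erythroid marker and only 2 platelet markers were tested, so those lists had no set test.

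Genes named in the text follow a rule fixed before the data were examined: Il17a and Il24; up to 10 genes in each direction with the largest changes among those past the main test; and, of each list, up to 4 members with the smallest p in the main test. No gene passed the main test. A second rule was therefore added after seeing the data, for the paired DESeq2 fit. It takes the 10 largest increases and 10 largest decreases among called genes that averaged at least 1 CPM and went the same way in all 3 pairs, outside immunoglobulin, T cell receptor, pseudogene, microRNA and X-inactivation genes, and the list members that fit called; 1 of these is not reported here. Of each list the member with the smallest p is always given; which of the other 3 are given was settled after their values were seen. Xist, Ddx3y, the MHC class II genes, the class-switched immunoglobulin genes, Ecm1, Tgm2, Igfbp4 and Timp1 were also chosen after their values were seen.

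The other settings chosen in advance were DESeq2 size factors, upper-quartile factors and library totals in edgeR, no low-count filter, a mean of at least 50 counts, DESeq2, limma-voom, the replicate block, an adjusted p under 0.1, a 2-fold limit, transcripts without summing, the neighbours of Il17a left out, and each library left out in turn. Added after seeing the data were edgeR's bias-adjusted quasi-likelihood method, transcripts under 300 nt left out, both number 1 libraries left out, and the paired DESeq2 fit without each pair. An alternative on another measure (uniquely assigned counts, FPKM or TPM) was listed in advance but not run, since the table gave 1 measure.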

Results

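The data are mRNA profiles of mouse splenic CD4+CD62L+ T cells, 3 from wild-type and 3 from Il17a knockout animals, after 3 days of culture toward the Th17 state, in which helper T cells make IL-17A. The wild-type libraries held 48278239, 47335736 and 48246568 estimated counts and the knockout libraries 49117016, 47573479 and 49743762. Between 14750 and 15302 genes had at least 10 counts. Values are in CPM, as mean ± SD with n = 3 per genotype unless given per library. Coordinates are on GRCm38 as annotated.

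**Figure D1:**
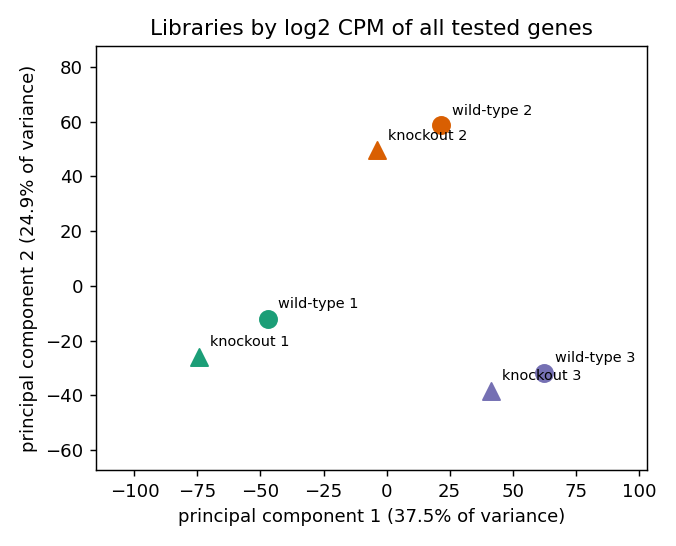
Principal components 1 (37.5% of the variance) and 2 (24.9%) of log2 CPM over the tested genes. Circles are wild-type and triangles knockout libraries, colored by replicate number. Libraries of the same number lie together.

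Libraries grouped by replicate number before genotype. Principal component 1, with 37.5% of the variance, placed wild-type 1 at -47.2 and knockout 1 at -74.3, and wild-type 3 at 62.4 and knockout 3 at 41.4. Component 3, with 14.2%, held the wild-type libraries at 33.7, 32.8 and 14.6 and the knockout libraries at -10.8, -45.8 and -24.4. The number 1 libraries also stood apart in Cd8a, the CD8 coreceptor chain, at 257 CPM in wild-type 1 and 425 CPM in knockout 1, against 33.7 to 66.1 CPM in the other 4. Sex-linked transcripts differed within the knockout group. Xist, transcribed from the inactive X of female cells, was at 567, 623 and 664 CPM in the wild-type libraries and at 2.58, 0 and 627 CPM in knockouts 1, 2 and 3. The Y-linked gene Ddx3y was at 44.5 and 38.0 CPM in knockouts 1 and 2, at 0 in knockout 3 and at 0.452 CPM or less in the wild-type libraries. Genotype and sex-linked transcripts thus differed together in pairs 1 and 2 and not in pair 3.

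The deleted gene was nearly silent in all 3 knockout libraries. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496), the signature Th17 cytokine, was at 160.6, 211.1 and 107.8 CPM in the wild-type libraries (159.8 ± 51.7). The knockout libraries held 57, 0 and 1 estimated counts, or 1.11, 0 and 0.0202 CPM; a count of 0 in knockout 2 allows up to 0.0614 CPM. The log2 change was -8.70 (SE 1.301). The adjusted p was 0.9999 in edgeR without the block and 0.217 with it, 0.00855 in DESeq2 and 4.44e-06 in the paired DESeq2 fit (log2 change -11.97, SE 2.09). Without knockout 1, which held 57 of the 58 knockout counts, edgeR gave a log2 change of -13.62 and an adjusted p of 0.0124. The counts match the genotype labels of all 6 libraries.

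**Figure D2:**
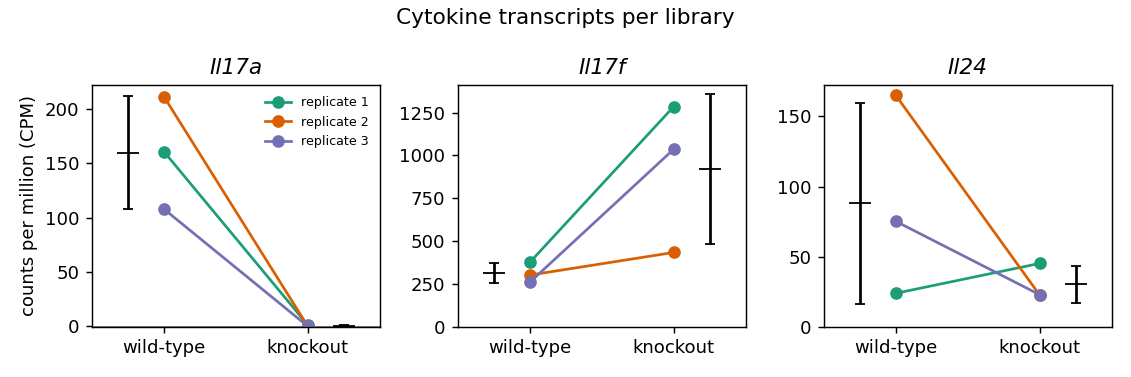
Il17a, Il17f and Il24 in CPM in each library. Lines join libraries of the same replicate number, and black bars give the mean ± SD of each genotype (n = 3). Il17a lay near 0 in every knockout library, Il17f was higher in the knockout of every pair, and Il24 was lower in pairs 2 and 3 and higher in pair 1.

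The series title presents IL-24 as a product of IL-17A signalling that feeds back on Th17 cells, which makes Il24 the first gene to compare. Il24 (ENSMUSG00000026420, chromosome 1, 130882074 to 130887454), an IL-10 family cytokine gene, was lower in the knockout in pairs 2 and 3, at 22.6 against 165.1 CPM and 22.8 against 75.2 CPM, and higher in pair 1, at 45.1 against 23.8 CPM. The group values were 30.2 ± 12.9 CPM in knockout and 88.1 ± 71.5 CPM in wild-type libraries, a log2 change of -1.54 (SE 0.66). The decrease did not pass the test: edgeR gave an unadjusted p of 0.0521 and an adjusted p of 0.9999, and the paired DESeq2 fit an adjusted p of 0.730 (log2 change -1.30, SE 0.94). With pair 1 left out, the paired DESeq2 fit gave a log2 change of -2.29 and an adjusted p of 2.38e-17, from a fit with 1 residual degree of freedom. Over all alternatives the Il24 log2 change ran from -2.40 to -0.42 and its adjusted p from 2.38e-17 to 1. Il22, another cytokine of this family, was also higher in the knockout in pair 1, at 89.9 against 36.2 CPM, and lower in pairs 2 and 3, at 5.34 against 6.49 and 5.34 against 13.4 CPM. Its unpaired log2 change was 0.84 (SE 1.18) and its paired DESeq2 change -0.12 (SE 0.70), neither past the test. The IL-10 family list, 8 tested members, had pair medians of 0.33, -0.33 and -0.44, with no member past the unpaired or paired tests on all 3 pairs. Its camera adjusted p was 0.412 in edgeR without the block, 0.366 with it and 0.424 on the paired DESeq2 statistics. Over the main test and its alternatives, the list passed, pointing down, in 3 of 28 settings: edgeR without wild-type 1, edgeR without both number 1 libraries, and paired DESeq2 without pair 1.

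Il17f, the closest relative of Il17a and its neighbour on chromosome 1 (ENSMUSG00000041872, 20777151 to 20784270), rose in the knockout in the paired DESeq2 fit. It was at 312 ± 59.1 CPM in wild-type and 918 ± 438 CPM in knockout libraries, and the log2 ratios were 1.77, 0.52 and 1.99 in pairs 1, 2 and 3. The paired DESeq2 change was 1.43 (SE 0.44, adjusted p 0.0433), and DESeq2 without the block gave an adjusted p of 0.0481. In edgeR the adjusted p of Il17f was 0.9999 without the block and 0.366 with it; in the paired DESeq2 fit without pair 1 it was 0.892. Of the 17 Th17 program genes, 2 rose in the paired DESeq2 fit. These were Il17f and Ccl20, the ligand of CCR6, with a paired change of 1.08 (SE 0.29, adjusted p 0.0123). Ccr6 itself was at 14.3 ± 3.99 CPM in wild-type and 21.97 ± 4.23 CPM in knockout libraries and did not pass. The list as a whole had pair medians of 0.36, 0.21 and 0.11 and a camera adjusted p of 0.253 in edgeR without the block and 0.196 on the paired DESeq2 statistics. It passed, pointing up, in 4 of 28 settings: DESeq2 without the block, edgeR without knockout 1, and paired DESeq2 without pair 1 or pair 2.

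Over the transcriptome, edgeR called 0 of 15121 genes between the genotypes, with 253 genes at an unadjusted p under 0.05 (123 higher and 130 lower in knockout, 1.67% of those tested). Limma-voom also called 0, with 276 at an unadjusted p under 0.05, and DESeq2 called 13, 8 higher and 5 lower. In simulated data with nothing changed DESeq2 called 34, but those libraries held no replicate structure, so the counts cannot be compared directly. With the replicate block edgeR called 0 (1471 unadjusted, smallest adjusted p 0.217), limma-voom called 0 (1642 unadjusted) and DESeq2 called 381 genes, 154 higher and 227 lower. In simulated data with known changes 23.3% of the paired DESeq2 calls were unchanged genes, and 25 genes were called when nothing had been changed. Of the 381 genes, 378 went the same way in all 3 pairs. The median log2 ratio of the 154 was 1.03, 1.02 and 0.88 in pairs 1, 2 and 3, and that of the 227 was -0.60, -0.52 and -0.52. The fit selected these genes from the same 3 pairs, and such selection favors agreement between pairs. Neither the shared direction nor the medians are therefore separate support. Leaving out pair 1, 2 or 3 gave 176, 264 and 149 called genes, of which 108, 148 and 96 were among the 381. The CPM ranges of the genotypes did not overlap for 929 genes, 6.14% of those tested; chance gives 10% for libraries with no pairing, a value that does not apply directly to paired libraries.

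Below, rose and fell refer to the paired DESeq2 fit, and changes are its log2 changes. None of these genes other than Igkc, Il17a, Il17f and mt-Nd4l passed without the block in DESeq2, and none passed in edgeR on all 6 libraries. Without knockout 1, Il17a passed in edgeR.

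Immunoglobulin genes made up 29 of the 154 genes that rose. Of 143 tested immunoglobulin genes 29 rose and none fell in the paired DESeq2 fit, and 16 of the 29 were among the 67 kappa light chain genes. The called share was 20.28%, against 2.52% of all tested genes. Estimated counts of genes with similar sequences are uncertain, so the 29 calls are not separate observations. In edgeR 0 of the 143 passed, with 30 at an unadjusted p under 0.05. Igkc, the kappa constant region, was at 113 ± 20.8 CPM in wild-type and 256 ± 8.94 CPM in knockout libraries, a change of 1.19 (SE 0.15, adjusted p 1.71e-11), with log2 ratios of 1.00, 1.02 and 1.56 in the 3 pairs. B cell markers were higher in the knockout for 12 of 12 members and 5 rose, among them Igkc, the kinase gene Blk (1.11), Ms4a1 (1.36) and Cd22 (0.92). The B cell list passed camera with a median log2 change of 1.12 (adjusted p 4.24e-04; adjusted p = 0.832 with an estimated correlation), and Igkc was the 1 member past edgeR without the block when adjusted over the list alone. Its pair medians were 0.98, 1.29 and 0.05, so that apart from Igkc the difference lay in pairs 1 and 2, the pairs that also differ in sex-linked transcripts. Cd22 went from 37.2 to 94.0 CPM in pair 1, from 14.4 to 36.7 CPM in pair 2 and from 8.11 to 8.40 CPM in pair 3. Without knockout 1 the camera adjusted p of the B cell list was 0.114.

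**Figure D3:**
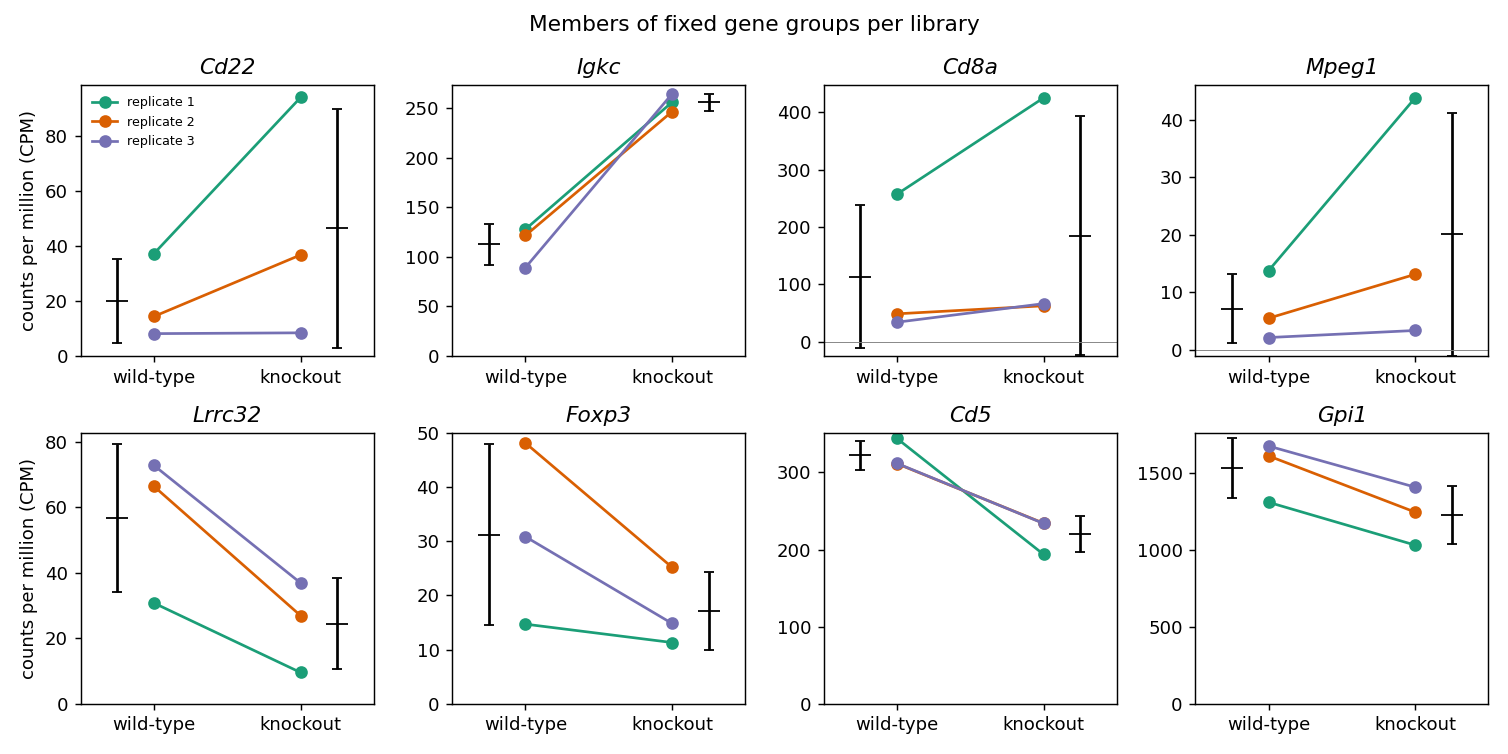
Members of the fixed gene groups in CPM in each library, with lines joining libraries of the same replicate number and black bars for the mean ± SD of each genotype (n = 3). Igkc was higher in every knockout library than in any wild-type library. Cd8a, Cd22 and Mpeg1 were highest in the number 1 libraries of each genotype, and Lrrc32, Foxp3, Cd5 and Gpi1 were lower in the knockout of every pair.

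CD8 T, NK and myeloid cell markers, lists of other cells that the selected population could hold, had medians above 0 in every pair. CD8 T cell markers had 2 of 6 members that rose, Cd8a (0.68) and the receptor gene Klrc1 (0.81). NK cell markers had 2 of 8, Klrd1 (0.68) and Klrk1 (0.70); Klrb1c, the member with the smallest unpaired p, was at 0.554 ± 0.260 and 1.14 ± 0.786 CPM. Myeloid markers had 4 of 12, Mpeg1 (1.22), Clec7a (1.34), Itgam (0.92) and Ctss (0.38). The paired edgeR camera test passed for the CD8 (adjusted p 0.00566), NK (0.0209) and myeloid lists (8.59e-05), each with an adjusted p = 0.560 with an estimated correlation, and none of the 3 passed in the main edgeR fit without the block. Without the block and with all 6 libraries, the myeloid list passed on DESeq2 and limma-voom statistics, and the NK list in edgeR with transcripts not summed. Pair medians were 0.35, 0.43 and 0.83 for the CD8 list, 0.07, 0.26 and 0.67 for NK and 0.18, 0.70 and 0.61 for myeloid markers. Without knockout 1, the library richest in Cd8a, the unpaired log2 changes of Cd8a, Klrc1, Klrd1 and Klrk1 were -0.82, -0.13, -0.02 and -0.53, and without knockout 2 that of Itgam was -0.50; these fits kept the partner library, and all 5 genes were higher in the knockout in every pair. The CD8 and NK lists share Gzma and Prf1, so they are not independent. Of 7 gamma-delta T cell markers 1 rose, Blk, which the B cell list also holds. The gamma-delta list had a camera adjusted p of 0.176 in edgeR without the block, 0.0603 with it and 0.00320 on the paired DESeq2 statistics. It passed in 6 of 28 settings, among them DESeq2 without the block, limma-voom with it, and edgeR without knockout 1 or without both number 1 libraries. No dendritic cell marker of 5 changed; Xcr1 had an unpaired log2 change of 0.55 (SE 0.61). Of the 2 tested platelet markers Itga2b fell (-1.19).

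Regulatory T cell genes included 4 that fell and 1 that rose among 15 tested. Lrrc32, which encodes the TGF-β-docking receptor GARP, fell by 1.33 (SE 0.18, adjusted p 1.31e-10), from 56.6 ± 22.7 to 24.4 ± 13.8 CPM, and was lower in the knockout of each pair. Foxp3, the lineage transcription factor, fell by 0.81, from 31.3 ± 16.7 to 17.1 ± 7.23 CPM, Tnfrsf18 (GITR) by 0.52 and Gpr83 by 1.15, whereas the integrin gene Itgae rose by 0.63. The list passed camera on the paired DESeq2 statistics at the preset correlation (adjusted p 0.00120) but not in edgeR with the block (0.0836, or 0.594 with an estimated correlation). Its pair medians were 0.01, -0.22 and -0.31, so pair 1 was not lower. Th2 genes had 3 of 10 members that fell: Il4ra, an IL-4 receptor chain, by 0.48, the transcription factor gene Nfil3 by 0.71 and the chemokine receptor gene Ccr4 by 0.45. This list's paired DESeq2 camera test pointed down (adjusted p 0.0247), and its median was -0.06 and its mean 0.04. It did not pass in edgeR with the block (adjusted p 0.347, or 0.8045 with an estimated correlation). The Th2 pair medians were 0.20, -0.36 and -0.30, so pair 1 went the other way. T cell identity genes had 3 of 14 that fell, Cd5 by 0.56, Cd6 by 0.37 and Cd2 by 0.48; the list passed camera on the paired DESeq2 statistics (0.00285) and in 9 of 28 settings, but not in edgeR with the block (0.0603). Cd5, an inhibitor of T cell receptor signalling, was at 322 ± 18.8 CPM in wild-type and 221 ± 23.3 CPM in knockout libraries. No naive T cell gene of 13 changed; Il7r was at 133 ± 34.1 and 174 ± 43.3 CPM.

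Of 16 pathogenic Th17 genes 3 rose, the chemokine genes Ccl3 (1.10) and Ccl4 (1.00) and the Th1 factor gene Tbx21 (0.74). Of 13 Th1 genes 2 rose, Tbx21 and Ifng (0.94), while Runx3 differed by -0.14 (SE 0.12) without the block. Of 20 T cell activation genes 3 rose, the checkpoint receptor genes Havcr2 (1.36) and Pdcd1 (0.94) and Egr3 (1.51). The 3 lists passed camera on the paired DESeq2 statistics (adjusted p 1.81e-04, 0.00298 and 0.0247) and not in edgeR with the block (0.0640, 0.0603 and 0.170). With an estimated correlation, run in edgeR only, camera's adjusted p with the block was 0.560, 0.560 and 0.686. Ifng, Ccl3, Ccl4 and Tbx21 were highest in the number 1 libraries, as Cd8a was. All 4 were higher in the knockout in every pair, with log2 ratios of 1.71, 0.17 and 0.86 for Ifng, 1.42, 0.56 and 1.26 for Ccl3, 0.99, 0.82 and 1.17 for Ccl4 and 0.81, 0.81 and 0.53 for Tbx21. Their unpaired log2 changes turned negative, to -1.11, -0.06, -0.15 and -0.43, without knockout 1 while its partner wild-type 1 stayed in, and were positive without both. No non-pathogenic Th17 gene of 7 changed; Il9 was at 4.32 ± 5.32 and 0.837 ± 0.685 CPM.

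Glycolysis and hypoxia genes were lower in the knockout in 19 of 20 members without the block and in 20 of 20 with it. The list passed camera with a median of -0.18 (adjusted p 0.0391; adjusted p = 0.832 with an estimated correlation) and in the paired edgeR fit (1.77e-05; adjusted p = 0.560 with an estimated correlation), and its pair medians were -0.27, -0.21 and -0.17. The members that fell were Gpi1 (-0.33) and Aldoa (-0.31), both enzymes of the pathway, Pfkm (-0.50), the glucose transporter gene Slc2a3 (-0.43) and the oxygen sensor gene Egln3 (-0.62); without wild-type 3 the unpaired change of Slc2a3 was 0.31. Cell cycle genes were higher in 28 of 29 members, with a median of 0.16 (camera adjusted p 0.00973; adjusted p = 0.832 with an estimated correlation). None of the 29 passed alone, with Tyms at 30.3 ± 3.90 and 37.5 ± 5.52 CPM, and the pair medians were 0.56, -0.11 and 0.13. Interferon-stimulated genes passed camera in the paired edgeR fit (adjusted p 1.19e-04; adjusted p = 0.560 with an estimated correlation), with pair medians of 0.42, 0.43 and 0.13. No member of that list passed alone; Cmpk2 was at 0.231 ± 0.123 and 0.849 ± 0.715 CPM. The unpaired call of the glycolysis list was lost without wild-type 2 (camera adjusted p 0.238), wild-type 3 (0.927), knockout 1 (0.806, with the direction turned to up) or knockout 2 (0.139), and that of the cell cycle list without wild-type 1 (0.973, with the direction turned to down), knockout 1 (0.0529) or knockout 3 (0.0776). The paired DESeq2 statistics kept the glycolysis list down without pair 1, 2 or 3 (2.19e-06, 8.88e-07 and 1.50e-08), whereas the cell cycle list was lost without pair 1 (0.939). Over the 28 settings the glycolysis list passed in 23, the cell cycle list in 22, the B cell list in 27, the interferon-stimulated and myeloid lists in 11 each, NK in 10 and CD8 in 9. These counts, like those out of 28 for other lists, repeat some tests. The 2-fold limit and edgeR's bias-adjusted method leave camera's values unchanged, and the 0.1 threshold only rereads the main test. Without wild-type 1 the number of lists past camera went from 3 to 9.

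**Figure D4:**
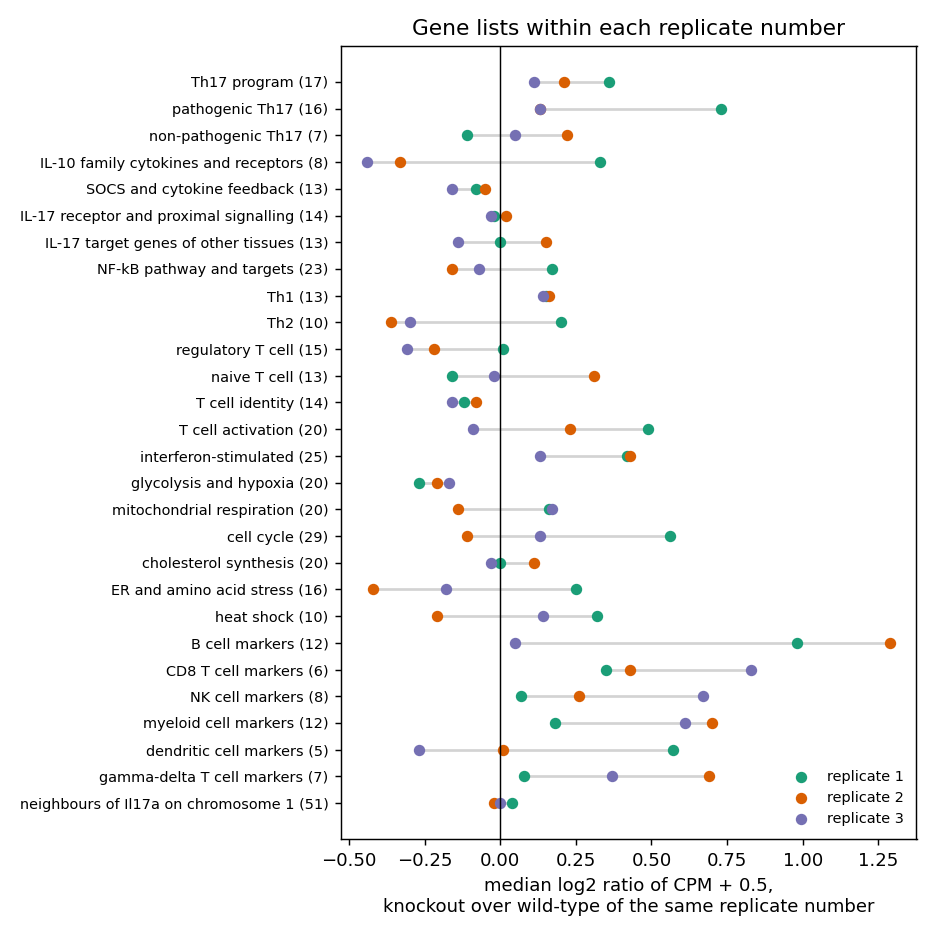
Median log2 ratio of CPM + 0.5, knockout over wild-type of the same replicate number, for each tested gene list (members tested in parentheses). Points are the 3 replicate numbers and grey lines their range. The glycolysis, T cell identity and SOCS lists lay below 0 in all 3. The Th17 program, pathogenic Th17, Th1, interferon-stimulated, B cell, CD8, NK, myeloid and gamma-delta lists lay above 0 in all 3.

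Negative regulators of cytokine signalling included 2 of 13 that fell, Cish (-0.38) and Socs2 (-0.51); Socs3, the main brake on STAT3, was at 448 ± 63.3 CPM in wild-type and 356 ± 72.1 CPM in knockout libraries and did not pass. ER and amino acid stress genes had 3 of 16 that fell, Ppp1r15a (-0.47), Ddit3 (-0.50) and Xbp1 (-0.47), with pair medians of 0.25, -0.42 and -0.18; the list passed camera on the paired DESeq2 statistics (0.00640) and in 8 of 28 settings, but not in edgeR with the block (0.0640). Of 20 cholesterol synthesis genes 1 rose, Idi1 (0.39). Of 13 IL-17 target genes known from other tissues 1 rose, Ccl20, and the median of the paired DESeq2 changes was -0.03 where the mean was 0.12. No gene changed among 14 of IL-17 receptor signalling, 23 of the NF-kB pathway, 20 of mitochondrial respiration and 10 of heat shock. Their members with the smallest p in the unpaired test were Zc3h12a at -0.23 (SE 0.18), Lta at -0.89 (SE 0.42), Cox7a2 at 0.26 (SE 0.23) and Hspa1b at -0.67 (SE 0.68). The IL-17 receptor list had a camera adjusted p of 0.983, the NF-kB list 0.454, the respiration list 0.253 and the heat shock list 0.819 without the block. The NF-kB list passed in 2 of 28 settings, the respiration list in 2 and the heat shock list in 1, each with a library or pair left out, as did the SOCS, IL-17 target and naive T cell lists in 1 each. The neighbours of Il17a had a camera adjusted p of 0.253, and of 51 tested only Il17f changed; this list passed, pointing up, in 1 of 28 settings, paired DESeq2 without pair 2. With camera's estimated correlation no list passed in edgeR (smallest adjusted p 0.832 without and 0.560 with the block). No list passed fry at an adjusted p under 0.05 without the block. With the block none passed fry's directional test, where the neighbours of Il17a had the smallest adjusted p (0.174). In its mixed test, which lets members go both ways, 9 of 28 lists passed, among them IL-17 receptor signalling (0.00905), Th2 (0.0115), regulatory T cell (0.0292) and the neighbours of Il17a (0.0435).

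The largest changes among genes called by the paired DESeq2 fit included effector and surface genes. Those that rose most were the chemokine gene Xcl1 (2.66), the receptor gene Vipr2 (2.33), Tdg (2.14), 3830403N18Rik (2.02), the granzyme genes Gzme (1.89) and Gzmd (1.87), Fn1 (1.88), Il1b (1.76), Serpinb9b (1.75) and Clnk (1.73). Besides Il17a, those that fell most were Gm21985 (-3.73), Gcnt4 (-3.27), Gdpd2 (-3.05), Serpinb5 (-2.29), Ly6g (-2.18), H19 (-2.10), the transglutaminase gene Tgm1 (-2.03), mt-Nd4l (-1.93) and 2610528A11Rik (-1.89). Most were weakly expressed. Xcl1 had the highest mean of these genes (102 CPM), but it reached 545 CPM in knockout 1 and only 17.4 CPM or less in knockouts 2 and 3. Without knockout 1 the unpaired log2 change of Xcl1 was -0.76, and without wild-type 3 that of H19 was 0.06, in fits that kept the partner library; within pairs Xcl1 was higher and H19 lower in the knockout in all 3. Gzmd and Gzme are near-identical copies, Ly6g belongs to a family of similar genes, Gm21985 is a readthrough model, and mt-Nd4l overlaps its neighbour and is under 300 nt, so the counts of these genes are uncertain.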

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

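In this part the paired fits in DESeq2 and limma-voom, edgeR's bias-adjusted method, the fit without transcripts under 300 nt, and the fits without number 1 libraries or without a pair were chosen after the data were seen. Of 2503 combinations of a named gene and an alternative, 2304 kept their direction and their side of the threshold, 176 passed the threshold where the main test did not, 0 were lost and 23 changed sign. Other scalings, filters, thresholds and summing, and edgeR's bias-adjusted method, left edgeR at 0 called genes and moved the median log2 change by -0.011, 0.009 and 0.060 for DESeq2 factors, upper-quartile factors and library totals; unadjusted counts ran from 205 to 630. The glycolysis list lost its call with no low-count filter (camera adjusted p 0.0693) and the cell cycle list with transcripts not summed (0.0872). Since no gene passed the main test, these fits show only that the count of 0 stayed.

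In edgeR the replicate block left 0 genes called and gave 7 gene lists past camera instead of 3. In limma-voom it gave 14, and in the bias-adjusted edgeR fit the same 7, since camera does not use the dispersion. The paired DESeq2 fit gave 381 genes, 154 higher and 227 lower, 15 lists, and Il17a at -11.97. Without pair 1 it gave 176 genes (96 and 80), 17 lists, Il17a at -13.88 and Il24 at -2.29. Without pair 2 it gave 264 (116 and 148), 16 lists and Il17a at -8.78. Without pair 3 it gave 149 (89 and 60), 13 lists and Il17a at -11.45. Gene calls under the block differed by tool, and DESeq2 also made the most false calls in simulated data. Without the block, DESeq2 gave 13 genes (8 and 5), 8 lists and Il17a at -8.74, limma-voom gave 7 lists, an adjusted p under 0.1 gave 6 lists, and leaving out both number 1 libraries gave 9. Without each library in turn, the called genes ran from 0 to 1, those lower from 0 to 1, lists from 3 to 9 and the Il17a change from -13.62 to -8.15. Beyond these, the block changed no call of the main test.

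Changes of sign came mostly from leaving out 1 library of a pair in a fit without the block, which keeps its partner and so shifts the balance of replicate numbers; no paired fit without a pair changed the sign of a gene other than Il22. With each library left out in turn, the lowest value coming without knockout 1 and the highest without wild-type 1, the log2 change ran from -0.13 to 1.74 for Klrc1, -0.82 to 2.16 for Cd8a, -0.02 to 1.3 for Klrd1, -0.53 to 1.88 for Klrk1, -0.06 to 2.24 for Ccl3, -0.15 to 2.22 for Ccl4, -0.43 to 1.94 for Tbx21, -1.11 to 2.93 for Ifng, -0.76 to 7.07 for Xcl1 and -1.82 to 1.74 for Il22. It ran from -0.50 without knockout 2 to 2.16 without wild-type 2 for Itgam, from -0.50 without knockout 3 to 0.12 without knockout 1 for Sdc1, and, between knockout 3 and wild-type 3 left out, from -1.16 to 0.31 for Slc2a3 and from -3.86 to 0.06 for H19. H2-DMa ran from -0.42 without knockout 1 to 0.07 without knockout 3, and was 0.06 without wild-type 1. Il22 also changed sign in limma-voom (-0.10), with the block in edgeR (-0.06), in bias-adjusted edgeR (where it reached 0.00) and in DESeq2 (-0.12), without both number 1 libraries (-0.90), and in the paired DESeq2 fit without pair 1 (-0.80) and pair 2 (-0.03). The cause was not tested, other than that number 1 libraries held the highest Il22. A fit on another measure, listed in advance, was not run, since the table gave 1 measure. Depth, from 47335736 to 49743762 counts, was alike in all libraries, and whether depth or spread limits the calls was not tested. In edgeR the bias-adjusted dispersion method took the adjusted p of Il17a from 0.9999 to 0.1805. The Il17a values of knockouts 2 and 3 lie at or below the floor of 3 counts.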

Other observations

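The tests of B cells and of sex for MHC class II, of B cells for Igkc, of the 3 explanations for Il17f, the splits for the count of called genes and for lists with the block, and the fry test without Il17f were chosen only after the result was seen; the others were set down before. Where a bound was met by less than the spread, over too few splits, or in a test that could not move, the explanation was left open; these limits were added after the values were seen. Tests on pair 3 rest on 1 pair of libraries, and all log2 ratios below are knockout over wild-type within a pair.

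Among the abundant genes that fell in the paired DESeq2 fit were 4 picked after their values were seen, which stand for no tested group. Ecm1, a secreted matrix protein, was lower in every pair, at 367, 1247 and 894 CPM in wild-type and 114, 728 and 405 CPM in knockout libraries (log2 change -1.21, SE 0.18, adjusted p 9.95e-09). The transglutaminase gene Tgm2 fell by 0.95 (adjusted p 1.09e-06), Igfbp4, an IGF-binding protein, by 0.82 (0.0263) and the metalloproteinase inhibitor gene Timp1 by 0.72 (0.0106), each lower in 3 of 3 pairs. None passed in edgeR, where the paired adjusted p was 0.271, 0.314, 0.466 and 0.422.

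Of 7 MHC class II genes 5 rose in the paired DESeq2 fit and were higher in the knockout in all 3 pairs, among them H2-Aa (log2 change 1.07), H2-Ab1 (1.08) and the invariant chain gene Cd74 (1.00). The other 2 did not pass: H2-DMa had log2 ratios of -0.15, 0.00 and -0.46 in pairs 1, 2 and 3, and H2-DMb2 of 0.63, 0.76 and -0.31. Class-switched immunoglobulin transcripts differed by gene. Ighg3 had log2 ratios of 0.92, 1.11 and -0.06 and did not pass. Ighg2c went from 1.15 to 25.04 CPM in pair 2 and from 11.4 to 99.5 CPM in pair 3, against 2.85 and 3.50 CPM in pair 1, and did not pass (paired DESeq2 adjusted p 0.162). Ighg1 passed (1.68, adjusted p 9.27e-04), as did the joining chain gene Igj (1.28, adjusted p 0.0419).

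The first pattern is the joint rise of B lineage and MHC class II transcripts and Igkc. In pairs 1 and 2 the B cell gene medians (1.03 and 1.32) and MHC class II medians (1.10 and 1.20) differed by at most 0.12, as more B cells in those knockout cultures would give, although cells selected as CD4+CD62L+ should hold few. In pair 3, where sex-linked transcripts did not differ and sex thus explains no difference, the MHC class II median was 0.68 and exceeded the B cell median by 0.63, but members spread by 0.68 (SD), so B cells stay open there, sex stays open for pairs 1 and 2, and myeloid cells, whose markers had a median of 0.61 in pair 3 and 0.18 in pair 1, stay open as untested. For Igkc, B cells alone are argued against, because its ratio exceeded the B cell median by 1.51 in pair 3. Plasma cells in pairs 2 and 3 may account for part of it, as the median of Ighg1, Ighg2c and Ighg3 was 1.32 or more in both, although Ighg3 was not higher in pair 3 and plasma cell gene medians were -0.06, 1.00 and 0.13 in the 3 pairs; their median of 0.02 over all pairs decides nothing, since its bound ignored the baseline, with Sdc1 already at 17.5 to 29.0 CPM in wild-type libraries.

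The second pattern is the higher Il17f in the knockout. Sex is argued against as the whole cause, since the log2 ratio was 1.99 in pair 3, where both libraries held Xist, though it could add to pairs 1 and 2. A rise of the whole Th17 program is argued against by a median of 0.13 over the other 16 genes. Donor DNA carried along with the deleted gene stays open. Of 50 other tested neighbours, 0 were called by paired DESeq2 (3 of 51 with Il17f at an unadjusted p under 0.05) and 0 by edgeR. Only 1.3 were expected (Fisher's exact p 0.638), too few to decide. In edgeR with the block the 50 gave an unadjusted directional fry p of 0.0214, pointing up, and 0.0151 in the mixed test. With Il17f, 31 of the 51 were higher and 20 lower in that fit, and the pair medians were 0.04, -0.02 and 0. Without the block the unadjusted directional fry p of the 51 was 0.248. The fry tests thus do not decide on donor DNA. The mixed result is not specific, since 9 of 28 lists passed that test. In the directional test the neighbours, with Il17f, had the smallest p of the 28 lists (0.00623), which did not pass after adjustment (0.174). The loss of IL-17A itself is an untested hypothesis that these data do not separate from donor DNA; returning IL-17A to knockout cultures would test it.

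The third pattern is that paired knockout effects across 11633 genes lay along the difference of the number 1 libraries from the others, with a Spearman correlation across genes, which are not independent, of 0.35. Effect and difference were computed from the same libraries, so they share values. The correlation thus also depends on which library of a pair lies further out, and it is a description only. The other 3 splits that part every pair reached at most 0.22, but 4 splits are too few to exclude chance, whatever bound was set. Removing marker, immunoglobulin and MHC class II genes left 0.35, yet it took out so few genes (11520 remained) that it could not have moved the value and decides nothing about other cell types. In pair 3 alone the correlation was 0.28, against 0.29 and 0.17 in pairs 1 and 2. Sex-linked transcripts did not differ in pair 3, so the sex of the cells does not explain the value there. Whether sex adds to pairs 1 and 2 cannot be told within that spread. A share of CD8 or other cells that differs between cultures is a candidate explanation left open, although cells selected as CD4+CD62L+ should hold few, as is a genotype effect.

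The 6 libraries allow 10 splits, the real one included, too few for a share under 0.05. In edgeR the real split called 0 genes and so did the highest other; all 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 253 genes and the highest other 2173, with 7 of 10 splits as large. That highest split set wild-type 1, knockout 1 and knockout 2 against the rest, and a count several times the real one points to a structure of the samples other than genotype. That split puts both libraries with Y-linked transcripts and both number 1 libraries on one side, so it does not separate sex from replicate number. For gene lists the real split gave 3 and the highest other 11, with 8 of 10 as large. With the numbers as pairs there were 4 splits that part every pair, also too few; edgeR gave 1471 unadjusted genes in the real split and 723 in the highest other, and DESeq2 called 381 and 31, with 1 of 4 as large in each. For gene lists with the block edgeR gave 7 in the real split and 11 in the highest other, with 2 of 4 as large, and DESeq2 15 and 12, with 1 of 4 as large.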
